A study of Mus musculus with 6 samples.

How the data were processed

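The series holds 6 RNA-seq libraries of sorted mouse hepatocytes, 3 labelled Axin2-positive and 3 labelled Axin2-negative, made with a stranded mRNA kit and sequenced on an Illumina instrument, per the labels' protocols. The authors deposited whole-number read counts per gene symbol for each library, for 17275 genes. Reads were aligned to mm10 with TopHat2 2.0.11, per the submitters' processing notes. The gene counter, its annotation and its use of strand are not given in the sources used here, so antisense and overlapping genes, and families of near-identical genes (Cyp2a, Cyp2c, Cyp3a, Gstm, Sult2a, Mup), are uncertain. The authors also deposited FPKM values per transcript, 1 per group, with p-values and q-values, made with Cuffdiff 2.2.2, per the submitters' processing notes and the file headers. Of 30165 transcripts there, 13843 had the status OK, and the smallest p-value was 5e-05, shared by 72 transcripts. Some gene symbols in the count table had turned into dates and were left as they were.

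Libraries were grouped by label, and the replicate number stands for the index that a library of each group shares. The labels do not say that libraries came from separate mice, so p-values of genes and of library totals measure the spread between these libraries. Whether the numbers pair the libraries was checked from the deviations from the group means. These correlated across genes at 0.68, 0.82 and 0.75 between libraries of the same number, all above 0.1. For the libraries labelled Axin2-positive 1, 2 and 3, the highest correlation with an Axin2-negative library of another number was 0.14, -0.60 and 0.01. The first of these also lies above 0.1. Deviations within a group sum to 0, so these values are not independent. The pairing comes from the shared index and this check. The libraries of replicate 2 held 7164 and 6759 reads of the Y-linked gene Ddx3y, and the other 4 held 0 to 3.

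Counts were tested with edgeR 4.0.16 in R 4.3.3 (default expression filter, TMM scaling, quasi-likelihood F test, group only), with Benjamini-Hochberg adjustment and a threshold of 0.05. CPM values use TMM-scaled totals, and log2 differences within a pair use an offset of 0.05 CPM. Gene lists, 27 in all, were fixed before the data were examined, and tested with camera in limma 3.58.1 where at least 5 members were tested, with a preset correlation of 0.01, with an estimated correlation, and with fry. With the preset correlation, camera compares list members with other genes as nearly independent. Its p-values then measure mainly the spread between genes, not that between libraries. With an estimated correlation, camera rests on the few residual degrees of freedom of the libraries. A high p there does not show that a list is unchanged. Alternatives fixed at the same time were DESeq2 1.42.0, limma-voom, other scalings and filters, a threshold of 0.01, a test against a fold of 1.5, the replicate block and leaving out each library. All fits of 2 pairs, the test of the 2 pair fit against a fold of 1.5, and the replicate block with an estimated correlation were added after the data were seen.

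On simulated counts with 100 genes changed by a fold of 2 and 100 by a fold of 4, the fit of 6 libraries recovered 3% and 56% of them over 12156 genes, with 4.84% of calls false. The counts for these 6 libraries were drawn without an effect shared by libraries of the same number. The real libraries share such an effect, so these shares may not hold for the planned fit. The 2 pair fit recovered 76% and 86% over 12214 genes with 19.4% of calls false, and against a fold of 1.5 it recovered 26% and 80% with 4.50% false.

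Named genes were 20 genes fixed in advance, the 8 largest called differences per direction (none in the planned fit; those of the 2 pair fit were picked after the data were seen) and up to 4 members with the lowest p in each called list, with the 3 most abundant members for markers of other cell types. In the authors' table a symbol listed more than once was represented by its OK transcript with the lowest p. Coordinates are from GENCODE annotation of GRCm38, and 99.1% of 20890 symbols shared with the authors' table overlapped the annotated gene.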

Results

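RNA was sequenced from hepatocytes of adult C57BL/6 mice that carried a doxycycline-dependent reporter of Axin2 promoter activity, in which cells with an active promoter make a nuclear green fluorescent protein. Axin2 is a transcriptional target and negative regulator of Wnt/β-catenin signalling. After 7 days of doxycycline, non-parenchymal cells were removed and the hepatocytes were sorted into fluorescent (Axin2-positive) and non-fluorescent (Axin2-negative) cells. Each group had 3 libraries, numbered 1, 2 and 3 by the sequencing index, and each index occurred once per group. The libraries labelled Axin2-positive held 103386648, 77994792 and 83294359 reads assigned to genes, and those labelled Axin2-negative 101814611, 75882611 and 85864467. Total reads, in units of 1e6, did not separate the groups (88.2 ± 13.4 against 87.9 ± 13.1, SD, n = 3 each; exact two-sided permutation test, p = 1). Neither did the share of reads in the 20 most abundant genes (25.2% ± 5.64 against 26.4% ± 5.43, SD, n = 3 each; exact two-sided permutation test, p = 0.8). With 3 libraries against 3, such a test cannot give a p below 0.1.

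Axin2 itself (chromosome 11, 108920349 to 108950783, GRCm38) was read first, because its promoter drove the sort. It reached 22.6 and 24.2 CPM in the libraries labelled Axin2-positive 2 and 3, against 3.74 and 5.74 CPM in the libraries labelled Axin2-negative 2 and 3. The library labelled Axin2-positive 1 held 2.40 CPM, below the 3.04 CPM of the library labelled Axin2-negative 1. The sorted gene therefore goes against the label of the library labelled Axin2-positive 1, and every direction below that includes it carries this limit. Over all 6 libraries Axin2 stood at 16.4 ± 12.1 CPM in the libraries labelled Axin2-positive and 4.18 ± 1.40 CPM in the others (SD, n = 3 each). Its log2 fold change was 1.97 (SE 0.81; edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p = 0.999).

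The main question of the design is which genes differ between Axin2-positive and Axin2-negative hepatocytes. Fitted as planned over all 6 libraries, edgeR's quasi-likelihood test called 0 of 12343 genes higher and 0 lower at an adjusted p under 0.05. At an unadjusted p under 0.05 it listed 279 genes, fewer than the 617 that chance alone would list. This fit leaves out the replicate number, and libraries of the same number were alike across the groups. The shortfall is therefore no sign that the groups do not differ. DESeq2 and limma-voom also called 0 genes, and so did the fit with the replicate number as a block, which listed 1132 genes at an unadjusted p under 0.05. Without the library labelled Axin2-positive 1 there were 1 higher and 5 lower calls, of genes named here after their values were seen. These were Gstm2 (higher) and Ak4, Bdh2, Car14, Sult5a1 and Tcf7l1 (lower).

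Genes known to mark hepatocytes around the central vein had high values in the libraries labelled Axin2-positive 2 and 3 and low values in the library labelled Axin2-positive 1. Glul, the glutamine synthetase gene, was at 339 and 1050 CPM in the former and 88.0 CPM in the latter, against 87.9, 46.9 and 119 CPM in the libraries labelled Axin2-negative 1, 2 and 3. The cytochrome P450 gene Cyp2e1 was at 1697, 11158 and 11164 CPM in the libraries labelled Axin2-positive 1, 2 and 3, against 1692, 2922 and 4033 CPM. Cyp1a2 gave 182, 2176 and 1238 CPM against 183, 368 and 296 CPM. The ammonium transporter gene Rhbg gave 0.730, 22.3 and 21.7 CPM against 1.20, 1.32 and 2.15 CPM. Oat, which encodes ornithine aminotransferase, gave 42.7, 1028 and 2004 CPM against 40.9, 280 and 606 CPM. Over 6 libraries the log2 fold change was 2.54 (SE 0.90) for Glul, 1.47 (SE 0.73) for Cyp2e1, 2.09 (SE 0.84) for Cyp1a2, 3.26 (SE 1.14) for Rhbg and 1.73 (SE 1.39) for Oat, each with an edgeR adjusted p of 0.999. For Lect2, Slc1a2, Tbx3, Lgr5, Rnf43 and Sp5 the log2 fold changes were 1.86, 3.50, 1.29, 2.64, 0.79 and 4.65, also at an edgeR adjusted p of 0.999. Single libraries moved several of these values by over 1.5 times. Leaving out the library labelled Axin2-positive 3 gave a log2 fold change of 1.33 for Glul, 0.79 for Oat, 1.69 for Slc1a2, 1.70 for Lgr5, 0.63 for Tbx3 and 0.46 for Rnf43. Values were 2.68 for Oat, 6.72 for Slc1a2, 4.54 for Lgr5 and 7.58 for Sp5 without the library labelled Axin2-negative 3, and without the library labelled Axin2-positive 2 it was 1.33 for Cyp1a2. With limma-voom it was 2.10 for Rhbg. Tbx2 stayed under 0.8 CPM in all 6 libraries.

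**Figure D1:**
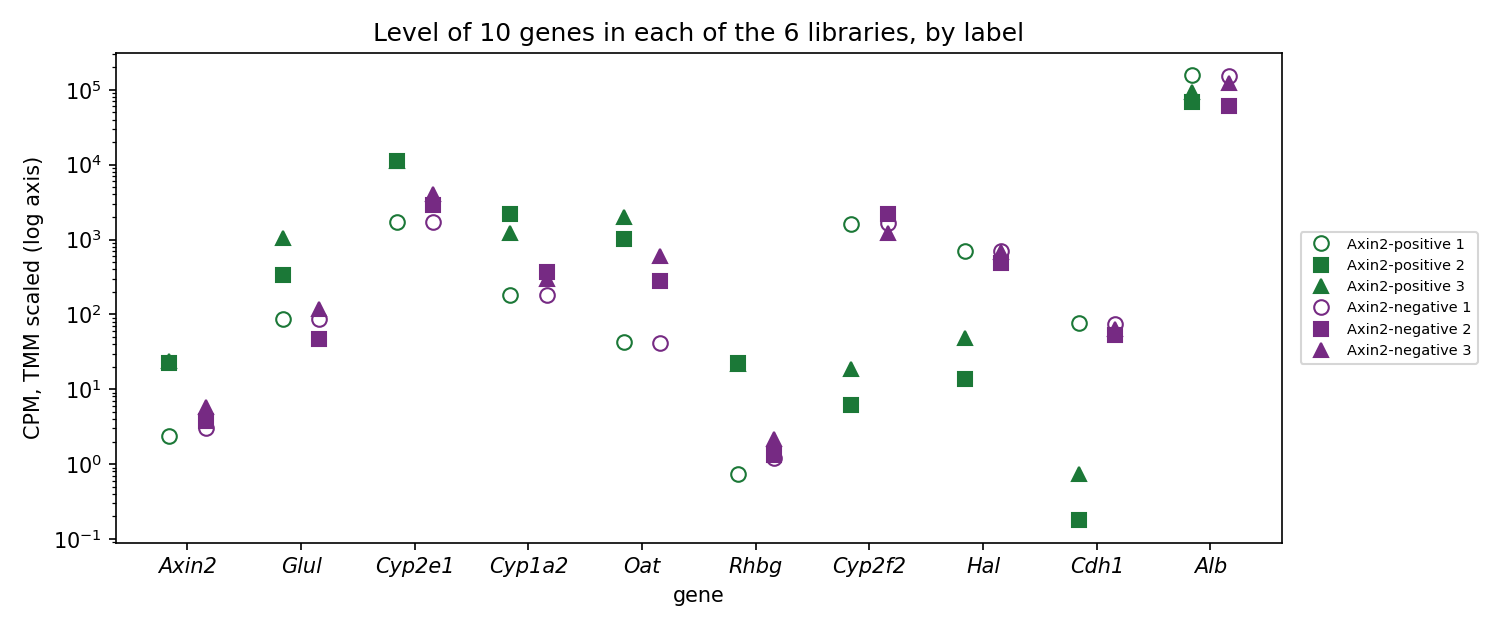
Level of 10 genes (CPM, log axis) in each library, with the libraries labelled Axin2-positive in green and those labelled Axin2-negative in purple. Open circles are replicate 1, squares replicate 2 and triangles replicate 3. The open green circle lies beside the open purple circle for most genes, as for Glul at 88.0 and 87.9 CPM. It lies lower for Axin2 (2.40 and 3.04 CPM) and Rhbg (0.730 and 1.20 CPM).

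Genes known to mark hepatocytes around the portal vein showed the opposite order. Cyp2f2 was at 6.17 and 18.8 CPM in the libraries labelled Axin2-positive 2 and 3, and at 1624 CPM in the library labelled Axin2-positive 1. The libraries labelled Axin2-negative 1, 2 and 3 held 1653, 2159 and 1233 CPM. The E-cadherin gene Cdh1 gave 75.6, 0.177 and 0.744 CPM against 73.5, 52.4 and 62.9 CPM. Hal, the first enzyme of histidine breakdown, gave 706, 13.9 and 48.6 CPM against 711, 479 and 675 CPM. Log2 fold changes over 6 libraries were -1.61 (SE 1.83) for Cyp2f2, -1.30 (SE 1.82) for Cdh1 and -1.28 (SE 1.31) for Hal, each with an edgeR adjusted p of 0.999. They were -7.08, -7.08 and -4.31 without the library labelled Axin2-positive 1, -1.04, -0.72 and -0.72 without Axin2-positive 2, and -1.05, -0.73 and -0.79 without Axin2-positive 3. With the replicate block they were -5.48, -4.79 and -3.16, and with limma-voom -4.89, -4.57 and -3.01. Pck1, a gluconeogenesis gene, was at 2869, 1685 and 3051 CPM against 2905, 3959 and 5095 CPM. Albumin (Alb) differed by -0.09 (SE 0.45) on the log2 scale, the fetal gene Afp by 0.09 (SE 0.81) and the biliary gene Sox9 by -0.46 (SE 1.85). For Alb, Afp and Sox9 these were -0.48, -1.01 and -6.01 without the library labelled Axin2-positive 1, and 0.21, 0.94 and 1.03 without the library labelled Axin2-negative 1. Sox9 was at 7.80, 0.0633 and 0.0465 CPM in the libraries labelled Axin2-positive 1, 2 and 3, against 8.28, 1.67 and 0.923 CPM.

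Differences were then taken within each replicate number. Across the 12343 tested genes, the log2 difference between the library labelled Axin2-positive and its Axin2-negative partner had an SD of 0.22 in replicate 1, 0.78 in replicate 2 and 0.62 in replicate 3. The differences of replicates 2 and 3 correlated across genes (r = 0.69), those of replicates 1 and 2 (r = 0.03) and of 1 and 3 (r = -0.01) hardly at all. Genes are not independent replicates, so these coefficients carry no p.

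**Figure D2:**
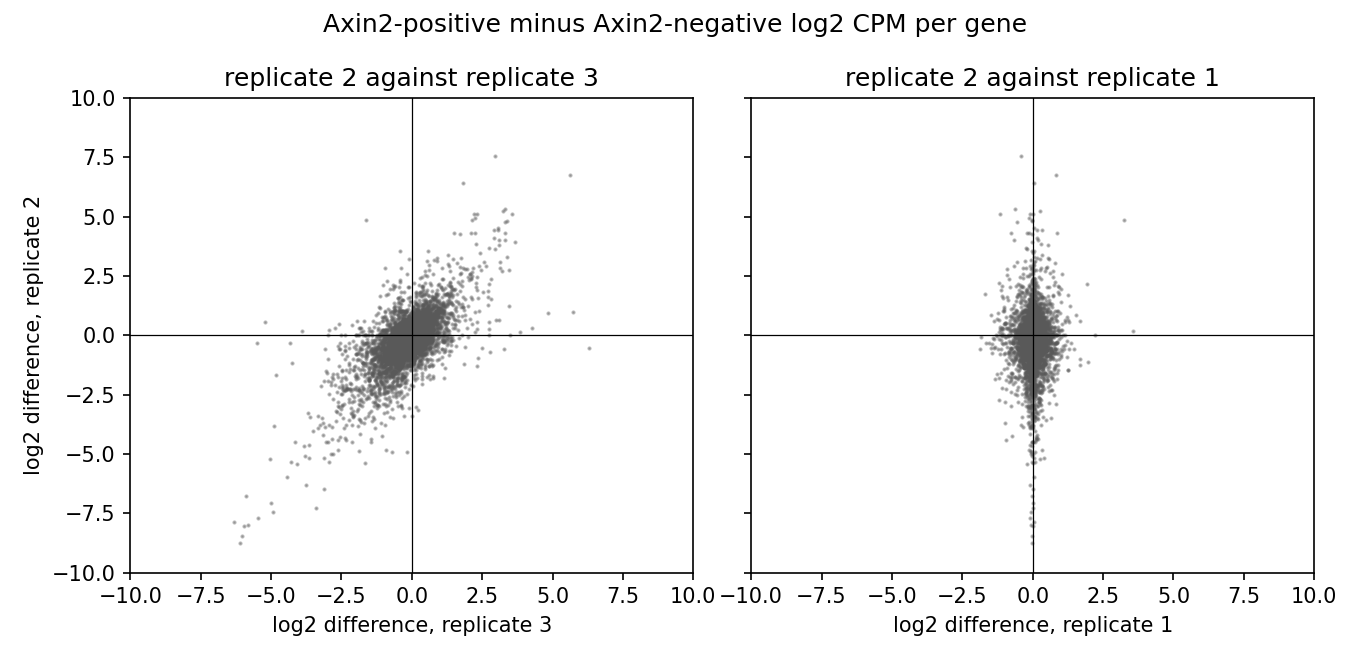
Log2 difference in CPM per gene, Axin2-positive minus Axin2-negative, in replicate 2 (vertical axis) against replicate 3 (left) and replicate 1 (right). Each point is 1 gene, with r = 0.69 on the left and 0.03 on the right.

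After these values were seen, a fit without both libraries of replicate 1, with the replicate number as a block, was added. It rests on 2 pairs and 1 residual degree of freedom. The pair was left out because it showed little difference, so the calls of this fit are not independent evidence of a difference between the groups. The fit called 425 genes higher and 497 lower in the libraries labelled Axin2-positive 2 and 3 (edgeR adjusted p under 0.05). Leaving out both libraries of replicate 2 or of replicate 3 instead gave 0 calls. Each of these fits joins replicate 1, with its little difference, to 1 other pair. Few calls were possible, so this count decides little. In simulated data 19.4% of the calls of this 2 pair fit were false, and 4.50% when tested against a fold of 1.5. The stricter test called 98 genes higher and 110 lower, and it was chosen for what follows after both counts had been seen. The simulation does not cover the choice of the pair that was left out. In the library pair of replicate 1, 50 of these 98 and 56 of these 110 genes had the same direction, with medians of 0.0028 and -0.0032 on the log2 scale.

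In that 2 pair fit, with edgeR's test against a fold of 1.5, Glul (log2 fold change 2.997, SE 0.13, adjusted p = 0.00302), Rhbg (3.68, SE 0.21, adjusted p = 0.00550), Cyp1a2 (2.32, SE 0.15, adjusted p = 0.00935) and Cyp2e1 (1.70, SE 0.13, adjusted p = 0.0128) were called higher. The sorted gene Axin2 was called as well (2.33, SE 0.15, adjusted p = 0.00935). Cdh1 (-7.00, SE 0.35, adjusted p = 0.00368), Hal (-4.45, SE 0.36, adjusted p = 0.0115) and Cyp2f2 (-7.23, SE 0.70, adjusted p = 0.0145) were called lower. So was Sox9 (-4.50, SE 0.44, adjusted p = 0.0164), on 5 and 4 reads in the libraries labelled Axin2-positive 2 and 3. Lgr5 (3.37, SE 0.64, adjusted p = 0.112), Sp5 (4.68, SE 0.72, adjusted p = 0.0628), Pck1 (-0.98, SE 0.14, adjusted p = 0.155) and Alb (-0.10, SE 0.14, adjusted p = 1) did not pass. Among the largest called differences were those of the long noncoding RNA Meg3, at 27.1 and 13.1 CPM against 0.199 and 0.217 CPM, and of Aldh1b1, at 0.165 and 1.76 CPM against 23.5 and 108 CPM. In replicate 1, Meg3 was at 0.134 and 0.0522 CPM and Aldh1b1 at 80.4 and 80.9 CPM.

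Of the 38 tested members of the pericentral hepatocyte list, 0 were called over 6 libraries, and 0 when adjusted over the list alone. The median log2 fold change was 1.20, and camera with a preset correlation of 0.01 placed the list above other genes (limma, adjusted p = 1.75e-14). With an estimated correlation the adjusted p was 0.620. The list median was 0.00 in replicate 1, 1.80 in replicate 2 and 1.38 in replicate 3. The 2 pair fit called 21 members higher and 0 lower, and 33 higher when adjusted over the list alone. Lect2, Gstm2, Cyp2c54 and Slc1a4 had the lowest p over 6 libraries. Gstm2 and Cyp2c54 belong to families of near-identical genes, so their counts are uncertain. The 49 genes of xenobiotic metabolism, which share members with that list, had a median of 0.49 (camera adjusted p = 1.78e-06, and 0.620 with an estimated correlation). The 2 pair fit called 12 of them higher and 1 lower, and 16 and 2 when adjusted over the list alone.

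The periportal list of 39 genes lay below other genes (median log2 fold change -0.71, camera adjusted p = 1.52e-12, and 0.620 with an estimated correlation), with 0 members called over 6 libraries, also when adjusted over the list alone. Its medians were -0.01, -1.23 and -1.13 in replicates 1, 2 and 3. The 2 pair fit called 17 members lower and 1 higher, and 22 and 1 when adjusted over the list alone. Asl and Igfbp2 were among those with the lowest p. The 40 genes of the urea cycle and amino acid catabolism had a median of -0.15 (camera adjusted p = 0.00186, and 0.620 with an estimated correlation), and it was not called without the library labelled Axin2-negative 3 (camera adjusted p = 0.0698). Of these genes the 2 pair fit called 2 higher and 6 lower, and 2 and 12 when adjusted over the list alone. Glul, which makes glutamine from ammonia, is in this list and had a positive log2 fold change, unlike Asl, Cbs and Got1.

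**Figure D3:**
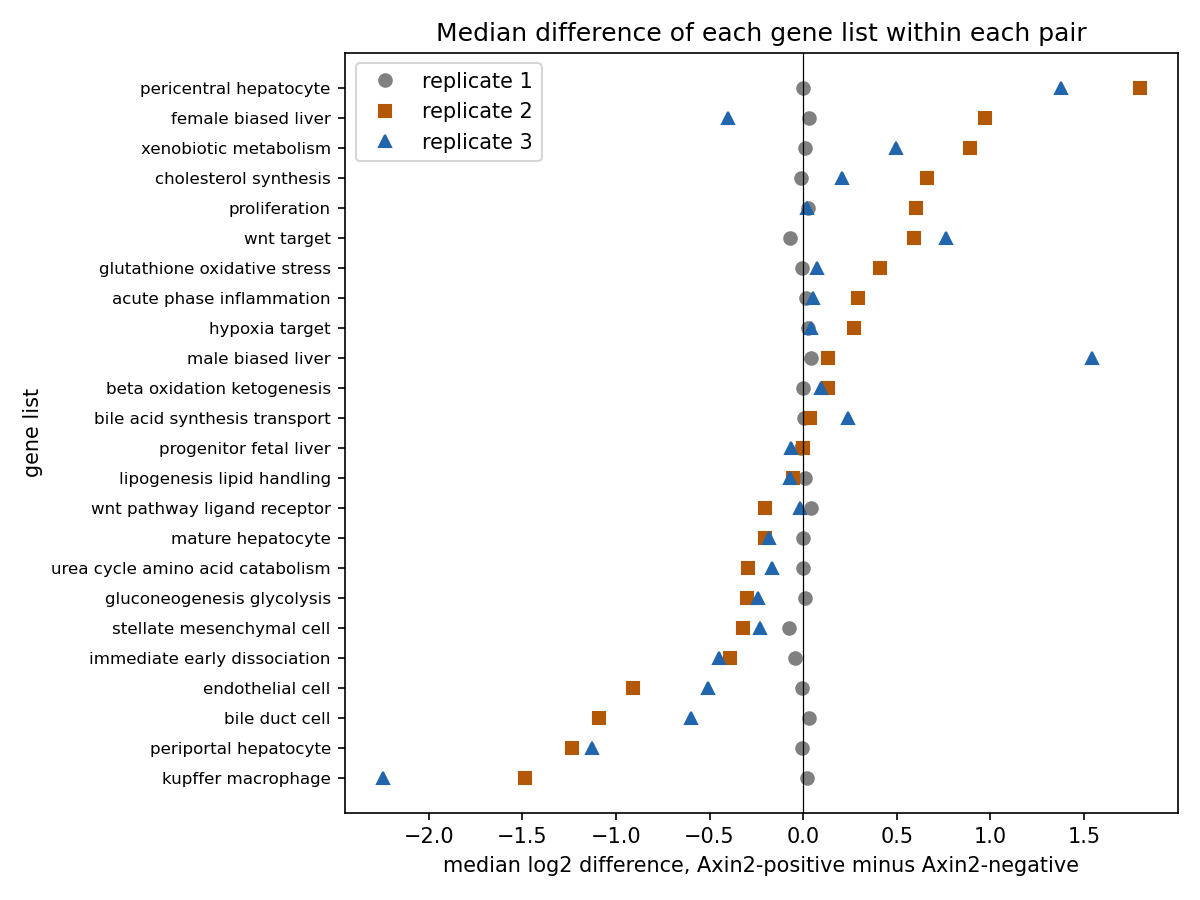
Median log2 difference in CPM of each gene list with at least 5 tested members, Axin2-positive minus Axin2-negative, within replicates 1 (circles), 2 (squares) and 3 (triangles). The medians of replicate 1 lie near 0, while the pericentral list is at 1.80 and 1.38 in replicates 2 and 3.

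Camera with the preset correlation also called cholesterol synthesis (median log2 fold change 0.25, adjusted p = 0.00415), proliferation (0.17, adjusted p = 0.0269, and 0.0614 with the replicate block) and beta-oxidation with ketogenesis (0.06, adjusted p = 0.0419) higher, and gluconeogenesis with glycolysis lower (-0.14, adjusted p = 0.0419). With an estimated correlation the adjusted p was 0.677, 0.662, 0.620 and 0.620. No member of these lists was called over 6 libraries, also when adjusted over the list alone. Each of these 4 calls was lost when certain single libraries were left out. Without the library labelled Axin2-negative 2, cholesterol synthesis turned lower (camera adjusted p = 0.558), and the adjusted p was 0.558 for proliferation, 0.374 for beta-oxidation and 0.181 for gluconeogenesis. Without the library labelled Axin2-positive 3 these were 0.257 for cholesterol synthesis, 0.257 for proliferation, 0.313 for beta-oxidation and 0.401 for gluconeogenesis. Proliferation (0.130) and gluconeogenesis (0.132) were also lost without the library labelled Axin2-negative 1, and cholesterol synthesis (0.0897) and beta-oxidation (0.0990) without the library labelled Axin2-positive 1.

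The 17 tested Wnt target genes had a median of 0.51, with pair medians of -0.07, 0.59 and 0.76, and were not called (camera adjusted p = 0.365). They were called higher with the replicate block (camera adjusted p = 0.00491, and 0.575 with an estimated correlation) and without the library labelled Axin2-positive 1 (0.0119). In the 2 pair fit, 4 Wnt targets were called higher and 3 lower, and 7 and 4 when adjusted over the list alone. The 24 immediate-early genes, which respond to cell dissociation, had a median of -0.20 and were not called (camera adjusted p = 0.142). They were called lower with the replicate block (camera adjusted p = 0.00540, and 0.575 with an estimated correlation), without the library labelled Axin2-positive 1 (0.0132) and without the library labelled Axin2-negative 2 (0.0298). Camera did not call Wnt ligands and receptors (median -0.04, adjusted p = 0.990), fetal or progenitor genes (-0.04, 0.878), bile acid synthesis and transport (0.04, 0.270), lipogenesis (-0.03, 0.878), glutathione and oxidative stress genes (0.20, 0.142), acute phase genes (0.11, 0.142), hypoxia targets (0.09, 0.270), male-biased genes (0.11, 0.542) or female-biased genes (-0.21, 0.839), each with its median log2 fold change and adjusted p. Its direction was higher for Wnt ligands and receptors and for female-biased genes, unlike the sign of their medians. Without the library labelled Axin2-negative 2, male-biased genes were called higher (camera adjusted p = 0.000256) and female-biased genes lower (0.00270), while without the library labelled Axin2-positive 2 female-biased genes were called higher (6.71e-05). By its reads of Y-linked Ddx3y and its near absence of Xist, replicate 2 was male, and replicates 1 and 3 were female. Either of these fits leaves sex unbalanced between the groups, so its calls do not separate the label from sex. Of the sex chromosome list 1 gene was tested.

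Markers of other liver cell types were counted in the same way. The 18 tested Kupffer cell genes had a median log2 fold change of -1.77 (camera adjusted p = 0.000199, and 0.620 with an estimated correlation), with pair medians of 0.02, -1.48 and -2.24. The list was not called without the library labelled Axin2-negative 3 (camera adjusted p = 0.0698). In the 2 pair fit 3 of 19 Kupffer genes were called lower, and 15 when adjusted over the list alone. The Kupffer gene Clec4f was at 1.05, 0.101 and 1.24 CPM in the libraries labelled Axin2-positive, against 0.909, 1.13 and 7.25 CPM. Mpeg1, the second most abundant of its list, was at 30.2, 95.05 and 38.2 CPM against 30.1, 101 and 41.3 CPM. The 7 tested bile duct genes had a median of -0.27 (camera adjusted p = 0.0269, and 0.620 with an estimated correlation). That call was lost without the library labelled Axin2-positive 2 (0.345), Axin2-negative 1 (0.0960) or Axin2-negative 3 (0.0715). Of the bile duct genes the 2 pair fit called 3 of 7 lower and 0 higher, also when adjusted over the list alone.

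Endothelial (27 genes, median -0.33, adjusted p = 0.182) and stellate genes (10 genes, median -0.22, adjusted p = 0.769) were not called by camera over 6 libraries, and the 2 pair fit called 0 members of either list, also when adjusted over the list alone. With the replicate block the endothelial list was called lower (camera adjusted p = 0.000358, and 0.575 with an estimated correlation). Its direction turned with the library left out: it was called lower without the library labelled Axin2-negative 2 (1.10e-07) or Axin2-positive 3 (0.00745), and higher without the library labelled Axin2-positive 2 (0.000146). The stellate list was likewise called lower without the library labelled Axin2-negative 2 (camera adjusted p = 0.0184) and higher without the library labelled Axin2-positive 2 (0.00504). The 27 mature hepatocyte genes had a median of -0.11 (camera adjusted p = 0.372). Of the lymphocyte list 0 genes were tested, and of the neutrophil, erythroid and platelet list 2.

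The authors' deposited table of transcript comparisons marked 97 transcripts at a q under 0.05, of 96 gene symbols. Higher values in Axin2-positive were held by 72 of these, and lower values by 24, in the authors' deposited table. Of the 93 that were also tested over 6 libraries, all 93 had the same sign and 0 were called by edgeR. The 2 pair fit, against a fold of 1.5, called 70 of 95 in the same direction and 0 in the opposite one. The group values of the authors' deposited table followed all 3 libraries per group: over 256 genes with a difference above 1 on the log2 scale in replicates 2 and 3, the median gap was 0.10 to the ratio of means over 3 libraries and 0.56 to that over replicates 2 and 3. Axin2 stood at 4.52 against 1.16 FPKM in the authors' deposited table (q = 0.00961), and Glul at 185 against 30.7 FPKM (q = 0.00961).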

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

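The 2 pair fits and the fits without replicate 2 or 3 were chosen after the data were seen. The counts of 0 higher and 0 lower genes stayed at 0 with DESeq2, limma-voom, RLE scaling or scaling by library totals alone, the other filters and thresholds and the replicate block. Leaving out 1 library gave 0 to 1 higher and 0 to 5 lower genes, the highest without the library labelled Axin2-positive 1. The 2 pair fit with the replicate block gave 425 higher and 497 lower genes, 98 and 110 against a fold of 1.5, 679 and 686 with DESeq2, and 629 and 685 with limma-voom. Without both libraries of replicate 2, or of replicate 3, it gave 0, where few calls were possible because replicate 1 showed little difference. With the labels of replicate 3 exchanged it also gave 0. That count was near certain beforehand, because the differences of replicates 2 and 3 correlate (r = 0.69) and then cancel. The 10 gene lists called by camera became 0 with an estimated correlation and 0 with fry. They also became 0 with an estimated correlation in the 2 pair fit and with the replicate block (a fit also added after the data were seen). In the 2 pair fit camera then rests on 1 residual degree of freedom, and its lowest unadjusted p, for the periportal list, was 0.0642. A count of 0 lists there says little against the lists. Other causes were not tested. The 10 lists became 12 with the replicate block, which changed no call of a gene. Leaving out 1 library gave 7 to 12 lists. The pericentral, periportal and xenobiotic lists were called in all 6 such fits, 7 called lists were lost in at least 1, and 6 others were gained in at least 1, 3 of these in both directions. The genes shared with the authors' table went from 0 to 86 in the 2 pair fit and 70 against a fold of 1.5.

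Of the log2 fold changes of the 20 genes fixed in advance, 16 kept their direction in every setting, but 12 of these 16 moved by over 1.5 times when 1 library was left out, such as Slc1a2 (1.69 to 6.72), Oat (0.79 to 2.68), Glul (1.33 to 3.03) and Cyp2f2 (-7.08 to -1.04). The other 4 were Axin2 (1.58 to 2.48), Cyp2e1 (1.16 to 1.95), Rhbg (2.85 to 3.82) and Lect2 (1.56 to 2.28). Afp reversed to -0.019 with limma-voom, -0.026 with the replicate block, -0.17 in the 2 pair fit (-0.16 with DESeq2, -0.17 with limma-voom and -0.17 against a fold of 1.5) and -0.13 without replicate 2. Leaving out 1 library gave -1.01 to 0.94 for Afp, -0.48 to 0.21 for Alb, -6.01 to 1.03 for Sox9 and -1.36 to 0.53 for Tbx2. Alb reversed to 0.10 without replicate 3. Leaving out 1 library leaves its replicate unbalanced between the groups. Afp was at 5.52 and 4.72 CPM in the libraries of replicate 1 and between 1.07 and 1.55 CPM elsewhere. The cause of the reversals was not tested. Libraries held 75882611 to 103386648 reads, and fits at lower depth were not run.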

Other observations

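The tests in this part were chosen after the result was seen, with the following exceptions. These are the correction for transcript length and GC content and the counts over other splits of the libraries. The camera and fry tests of gene lists, including camera with a single library left out, were also fixed in advance.

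The genes Elovl3 and Xist were singled out after their values were seen. Elovl3 was at 818 and 577 CPM in the libraries of replicate 2 and between 0.267 and 2.80 CPM in the other 4. Xist was between 367 and 606 CPM in replicates 1 and 3 and at 0.0507 and 0.0622 CPM in replicate 2. Within replicate 3, the female-biased gene Cyp3a16 was at 335 CPM in the library labelled Axin2-positive and at 6.27 CPM in its partner, and it did not exceed 2.51 CPM elsewhere. The female-biased list as a whole had a median log2 difference of -0.40 in that pair and the male-biased list 1.54, against 0.97 and 0.14 in replicate 2. The 0.97 is the value of Cyp3a16 itself, on 25 and 11 reads in replicate 2, so that median rests on counts near the floor. The reads of Cyp3a16 may be shared with near-identical Cyp3a genes, and no explanation is weighed here; the list of female-biased genes as a whole was not called among the 10 lists (with fry, 0 lists were called). Without the library labelled Axin2-positive 2 it was called higher (camera adjusted p = 6.71e-05), and without the library labelled Axin2-negative 2 lower (0.00270). Either of these fits leaves sex unbalanced between the groups, since the reads of Y-linked Ddx3y lay almost only in replicate 2.

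The library labelled Axin2-positive 1 lay close to the library labelled Axin2-negative 1. A swap of labels with the library labelled Axin2-negative 2 or 3 would need pericentral levels there near those of Axin2-positive 2 and 3. Of the libraries labelled Axin2-negative, 0 had such levels. An exchange between both libraries of replicate 1 cannot be seen this way, since their mean pericentral levels were alike (6.67 and 6.72 log2 CPM). Such an exchange would not account for their closeness. Nor would it account for the missing pericentral level, which was 8.82 and 8.87 log2 CPM in the libraries labelled Axin2-positive 2 and 3. The chi-square per degree of freedom between both libraries was 2.64 (95% bootstrap interval 2.12 to 3.30), against 24.4 or more for any other 2 libraries, so 1 library sequenced 2 times and 2 libraries of the same RNA cannot be told apart, since the spread between runs was not measured. Tubes with cells or RNA of the same makeup cannot be told apart from these either, since the SD of 0.22 for the log2 differences over genes in no list restates the closeness and decides nothing. A wrong label on this library alone, and a real lack of difference in that replicate, were not tested.

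In replicates 2 and 3, pericentral genes were higher and periportal genes lower under the Axin2-positive label. More RNA of other cell types under the Axin2-negative label would lower all hepatocyte genes alike, but the pericentral median exceeded that of mature hepatocyte genes by 1.65 (interval over genes 1.28 to 2.12), with a lower bound of 1.38 in replicate 2 and 1.17 in replicate 3. Removing a trend with transcript length or GC content left the median at 1.52 (interval 1.09 to 1.94). A hypothesis that the sort enriched pericentral hepatocytes in these 2 replicates may hold, but it was found and examined on the same data, and replicate 1 does not show it.

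The Kupffer median was lower in the same libraries, and a lower share of every non-parenchymal type alike would move the markers of these types together. In replicate 3 the Kupffer median lay apart from the endothelial one by -1.74 (interval over genes -2.02 to -1.19) and from the stellate one by -2.01 (-2.31 to -1.42). This argues against such a share as the whole of the difference in that pair only if each list reflects its own cell type alone, which was not tested. Of the 3 most abundant endothelial genes, Gata4 was not lower in that pair (11.1 against 9.84 CPM). Aqp1 (15.8 against 23.4 CPM) and Stab2 (15.5 against 20.9 CPM) were lower. In replicate 2 the same gaps were -0.58 (-1.39 to 0.40) and -1.16 (-1.78 to 0.11), so a lower share of every type and one of Kupffer cells alone cannot be told apart there. The gap in replicate 3 rests on 1 pair, in which the library labelled Axin2-negative 3 held 7.25 CPM of Clec4f, and without that library the Kupffer list was not called (camera adjusted p = 0.0698). A different share of Kupffer cells or of their RNA between the sorted populations stays open and was not tested.

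With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 0 higher and 0 lower genes and the highest other split 2 and 0. With real counts of 0, every split gives as many (10 of 10), which says nothing. The real split gave 10 called lists, the highest other split 13, and 4 of 10 splits gave as many. The real split parts the libraries of all 3 replicate numbers, and the other 3 splits that do so gave 10, 2 and 1 lists. The one with 10 is the real split with the labels of replicate 1 exchanged. The remaining 6 splits part 1 pair and so set whole replicates against each other, with 3 to 13 lists; the highest set both libraries of replicate 1 and the library labelled Axin2-negative 3 against the rest.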
